A study of Mus musculus with 40 samples.

How the data were processed

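The series measured mouse bladder urothelial cells grown as organoids, either wild type (WT) or labelled as double knockouts (dKO) of Kmt2c and Kmt2d, which encode the histone H3K4 methyltransferases of enhancers. The RNA-seq part, which was analysed here, compared cells given the solvent DMSO with cells given MI-503 at 1 µM for 4 days. MI-503 is a small molecule that blocks binding of menin to the methyltransferase KMT2A. Per the labels, polyA RNA was sequenced from 8 libraries in 4 groups of 2: WT DMSO, WT MI-503, dKO DMSO and dKO MI-503. The other 32 of the 40 samples in the series, made by PRO-cap, ChIP-seq and CUT&RUN, were not analysed here. Libraries were grouped by genotype and treatment as their labels give them. The labels do not state whether replicates were separate cultures, lines or days, so every p-value measures only the spread between these libraries.

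The deposited table holds raw read counts per Ensembl gene, with no normalization: all values are whole numbers, and the column totals differ. The authors' processing notes name STAR, Bowtie2, MACS3, deepTools and SICER and the builds GRCm38 and mm10 for the whole series. Tool versions, the counting program, its strand setting and the annotation release are not given in the sources used here, so values of overlapping or antisense genes and of close paralogs are uncertain. Counts cover a whole gene and cannot show the loss of single exons. The table has 53465 gene identifiers, of which 53274 had a symbol in the reference name table, and 1 row with no identifier and no number was left out. Positions were matched by symbol to RefSeq genes of GRCm38.p6, and 15513 of the genes tested had one. Library totals ran from 58113705 to 68571176 counts. A count of 0 in a library allows up to 3 counts, or 0.0438 to 0.0516 CPM by library total, before TMM scaling. Such floors and the 95% intervals given for counts of 1 to 3 cover counting error only.

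Counts were fitted in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr by group (minimum count 10, minimum total 15) kept 16921 genes and left out 36544. TMM factors ran from 0.892 to 1.06, and the WT DMSO libraries had the lowest, 0.896 and 0.892. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, which leaves 4 residual degrees of freedom, and the biological coefficient of variation was 5.14%. The contrasts were dKO against WT in DMSO, MI-503 against DMSO in WT, the same in dKO, the difference of these MI-503 effects (the interaction), and dKO against WT in MI-503. The two-sided edgeR F test was adjusted by Benjamini-Hochberg over the genes tested in each contrast, with a threshold of 0.05, and genes past it are called here risen or fallen. Standard errors (SE) are the absolute log2 fold change over the square root of F. Fold changes use a prior count of 0.125, and CPM are scaled by TMM. The model pools the spread of all genes. An exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.33.

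Gene lists, contrasts, tests, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. Of the 35 lists, 34 had at least 3 tested members. List members left out by the filter were not tested, and numbers of list genes are those tested unless stated. They were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01) against all other genes, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were alternatives. The former takes its p on the 4 residual degrees of freedom, so a call can end there without correlation between members. Changes of list members are given with the p adjusted over all genes, and counts adjusted over the list alone are added where they differ. The rule for named genes covered every contrast but dKO against WT in MI-503. Per contrast, it took the 5 genes with the largest change in each direction among those that passed. The rule asked for a mean of at least 5 CPM, a proper symbol and, except in the interaction, no overlap between the groups. It added 3 genes with the smallest adjusted p from lists that passed or had at least 3 called members, the 5 largest inverse changes per direction, and Kmt2c, Kmt2d, Kmt2a and Men1. Markers of other cell types were among the fixed lists. Some genes named by the rule are not reported here. The ER chaperone, cytosolic heat-shock and ATF4 target lists, the tests by chromosome and the tests of genes with all-or-none expression were chosen after values were seen, as were the thresholds of the latter.

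For contrasts that share libraries, 50 simulations of unchanged groups gave the correlation and the covariance that sharing alone produces. The alternatives were RLE size factors, library size only, DESeq2 1.42.0, no filter, a stricter filter, only the groups compared, a replicate block, and each library left out in turn. For the lists, the medians with library size only were added after the data were seen. The fit was tested on simulated data with 50 genes changed per fold. For dKO against WT in DMSO, 56% of 1.3-fold, 62% of 1.5-fold, 70% of 2-fold and 94% of 4-fold changes were recovered. Of the 16331 genes tested there, changed ones included, 6 unchanged genes were called. For the interaction the shares were 20%, 60%, 66% and 82%, with 9 unchanged genes called among the 16315 tested. A list raised 1.3-fold was called and 0 other lists were. The simulated genes were drawn independently of each other, so this cannot show false list calls that arise from correlated genes. Few genes were changed there, whereas 65.4% were called in dKO against WT in DMSO and 46.8% in the interaction. The adjusted threshold is stricter when few genes change, so the recovered shares do not carry over to these data. Scaling by TMM with most genes moving was not tested either. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.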

Results

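Kmt2c encodes an H3K4 methyltransferase of enhancers, and its RNA was lower in the libraries labelled dKO, though far from absent. Kmt2d encodes its paralog, and its RNA was not lower in those libraries but higher. Kmt2a, which encodes the methyltransferase that menin binds, and Men1, which encodes menin, were both higher in the libraries labelled dKO. MI-503 was followed by less Kmt2c, Kmt2d and Kmt2a RNA and more Men1 RNA in both genotypes. Values are TMM-scaled CPM as mean ± SD over the 2 libraries of a group, and coordinates are those of GRCm38.p6.

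Kmt2c (ENSMUSG00000038056, chromosome 5, 25271795 to 25498855) measured 111 ± 0.476 CPM in WT DMSO, 61.0 ± 0.980 in WT MI-503, 53.8 ± 2.08 in dKO DMSO and 28.2 ± 2.24 in dKO MI-503. It fell in dKO against WT in DMSO (log2 fold change -1.04, SE 0.059, adjusted p = 2.6e-09) and in MI-503 (-1.11, adjusted p = 2.89e-09). Kmt2d (ENSMUSG00000048154, chromosome 15, 98831669 to 98874077) measured 91.0 ± 6.26, 70.8 ± 7.15, 122 ± 15.7 and 95.3 ± 12.4 CPM in the same order. It rose in dKO against WT in DMSO (0.43, SE 0.10, adjusted p = 0.00166) and in MI-503 (0.43, adjusted p = 0.00226). The counts cover all exons and which exons were deleted is not given in the sources used here, so gene-level RNA does not show whether either knockout is complete, and the groups are called labelled dKO.

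Kmt2a (ENSMUSG00000002028, chromosome 9, 44803355 to 44881352) rose from 132 ± 1.35 to 149.8 ± 0.592 CPM (log2 fold change 0.18, adjusted p = 0.00408) in DMSO and fell to 86.8 ± 3.33 CPM with MI-503 in WT (log2 fold change -0.60, adjusted p = 7.15e-08) and to 119.8 ± 4.997 in labelled dKO cells (-0.32, adjusted p = 6.07e-05). Men1 (ENSMUSG00000024947, chromosome 19, 6334979 to 6340894) rose from 15.7 ± 1.76 to 30.8 ± 1.66 CPM (log2 fold change 0.97, adjusted p = 2.71e-07) in DMSO. With MI-503 it rose to 33.2 ± 1.19 CPM in WT (1.08, adjusted p = 6.67e-08) and to 45.8 ± 4.08 in labelled dKO cells (0.57, adjusted p = 4.23e-05). With MI-503, Kmt2c fell by similar amounts in WT (-0.86, adjusted p = 1.21e-08) and in labelled dKO cells (-0.93, adjusted p = 2.31e-08), and the difference did not pass (-0.072, adjusted p = 0.529). Kmt2d fell in WT (-0.36, adjusted p = 0.00522) and in labelled dKO cells (-0.36, adjusted p = 0.0066), and its difference did not pass either (adjusted p = 0.997). The calls of Kmt2d with MI-503 depended on single libraries: the call in WT ended without WT DMSO replicate 1 or WT MI-503 replicate 2, where the log2 fold change was -0.29 and -0.27, and that in labelled dKO cells without dKO DMSO replicate 2 or dKO MI-503 replicate 2, where it was -0.22 and -0.23.

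**Figure D1:**
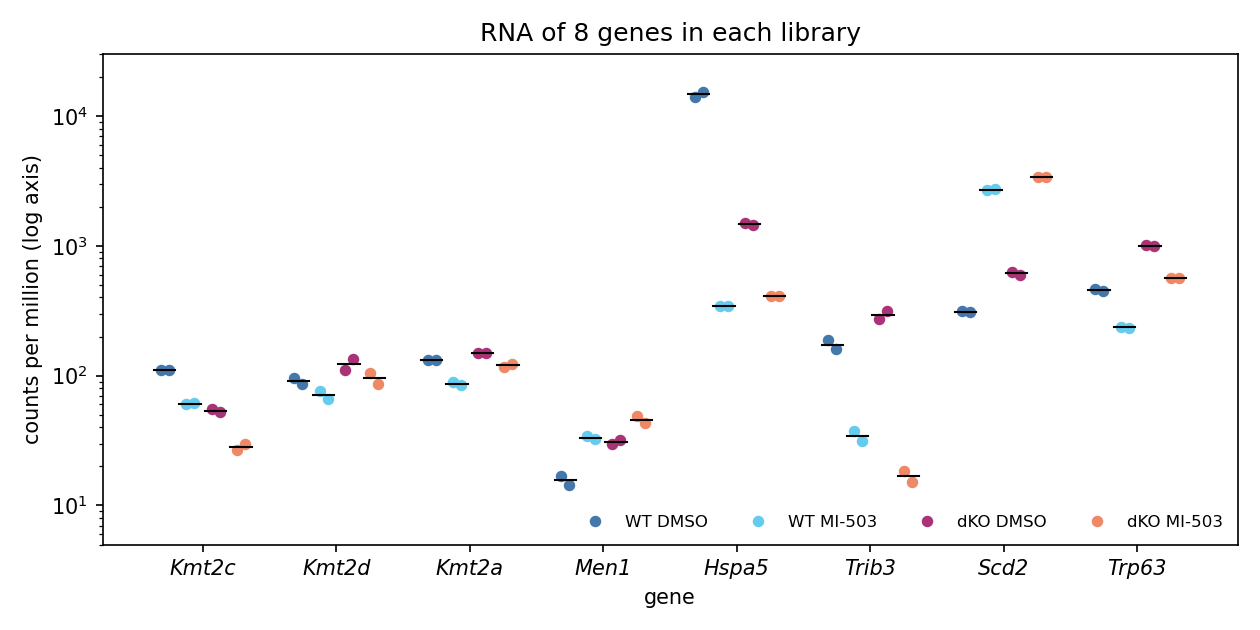
CPM (log axis) of 8 genes in the 8 libraries, with points for libraries and bars for group means. Kmt2c lay lower in both groups labelled dKO, whereas Kmt2d did not, and Hspa5 was highest in WT DMSO.

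In DMSO, the libraries labelled dKO had more RNA of the tested genes of neurons, developmental regulators and basal epithelium, and less RNA of unfolded protein response and p53 target genes, though none of these list calls held with an estimated correlation. The tests of the last 2 lists between the genotypes in MI-503 did not pass. Slitrk5, which encodes a neuronal transmembrane protein, and Gap43, a protein of nerve growth cones, were almost silent in WT. Pak3, which encodes a kinase of neurons, and the imprinted gene Peg10 went the opposite way. Trp63, the master regulator of basal epithelium, was higher, as was the laminin receptor subunit Itga6. The folding helper Creld2 and the cell-cycle inhibitor Cdkn1a, a p53 target, were lower.

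Of 16921 genes tested, 5017 rose and 6053 fell, 1773 and 2048 of them by at least 2-fold, and 5851 did not pass. The split was 45.3% higher among the calls, but most calls were higher with only the groups compared (50.9%), the stricter filter (51.2%), no filter (52.0%) and library size only (61.7%), which moved the median of all genes by 0.23. Slitrk5 had 0 counts in WT DMSO and 1777 in dKO DMSO, at least 526-fold higher against a floor of 3 counts in the group. Gap43 had 3 counts against 2075, a ratio of 614 (95% counting interval 210 to 2981). Mill1, a gene like those of MHC class I, rose from 0.229 ± 0.0903 to 65.4 ± 2.63 CPM (log2 fold change 8.14, adjusted p = 1.11e-14). Myh10, which encodes a nonmuscle myosin, rose from 0.443 ± 0.0183 to 62.8 ± 0.948 CPM (log2 fold change 7.14, adjusted p = 1.19e-14). The repressor gene Klf12 rose from 0.0576 ± 0.0354 to 16.0 ± 1.26 CPM. Pak3 had 1 count in dKO DMSO against 7868 in WT, a ratio of 8861 (1590 to 350022). Peg10 had 3 against 2169, a ratio of 814 (278 to 3951). Derl3, which acts in the removal of misfolded proteins, fell from 215 ± 3.66 to 0.683 ± 0.192 CPM (log2 fold change -8.31, adjusted p = 4.12e-15). Adtrp, which encodes a membrane-bound hydrolase, fell from 13.5 ± 0.0324 to 0.0298 ± 0.0223 CPM, and Ppp1r9a, an actin-binding scaffold gene beside Peg10, from 11.6 ± 0.371 to 0.0373 ± 0.0330 CPM.

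Of the 34 lists, 13 passed with camera at the preset correlation, 11 upward and 2 downward, whereas 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05, and 24 passed with fry. Of 32 ATF4 and unfolded protein response genes, 9 rose, 21 fell and 2 did not pass. The median was -0.88 (camera adjusted p = 4.27e-16, adjusted p = 0.107 with an estimated correlation). Creld2 fell from 753 ± 16.9 to 39.8 ± 0.445 CPM (log2 fold change -4.24, adjusted p = 5.3e-15). Manf, another secreted folding factor, fell from 1184 ± 68.2 to 79.7 ± 2.93 CPM (log2 fold change -3.89, adjusted p = 9.53e-15). Between the genotypes in MI-503, of the same 32 genes, 7 rose, 15 fell and 10 did not pass (8 and 15 adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.313, adjusted p = 0.609 with an estimated correlation). Both WT DMSO libraries stood apart: ER chaperone genes (ER, endoplasmic reticulum) took 4.32% and 4.65% of their TMM-scaled counts, against 0.456% to 0.591% in the other 6 libraries. Of 26 p53 target genes, 4 rose, 18 fell and 4 did not pass. The median was -0.85 (camera adjusted p = 3.83e-07, adjusted p = 0.153 with an estimated correlation). Btg2, which slows the cell cycle, fell from 351 ± 4.97 to 63.6 ± 0.903 CPM (log2 fold change -2.46, adjusted p = 4.06e-14). Cdkn1a fell from 792 ± 32.2 to 259 ± 4.42 CPM (log2 fold change -1.61, adjusted p = 4.24e-12). Between the genotypes in MI-503, the same 26 genes did not move 1 way: 9 rose, 8 fell and 9 did not pass (10 and 8 adjusted over the list alone). The median was 0.12 and the mean -0.030 (camera adjusted p = 0.517, adjusted p = 0.762 with an estimated correlation). The upward test and median differed in sign from the mean.

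Of 21 basal urothelial markers, 16 rose, 2 fell and 3 did not pass. The median was 0.76 (camera adjusted p = 8.26e-07, adjusted p = 0.153 with an estimated correlation). Itga6 rose from 1028 ± 20.1 to 2884 ± 54.9 CPM (log2 fold change 1.49, adjusted p = 7.13e-12). Trp63 rose from 456 ± 7.69 to 1005 ± 19.4 CPM (log2 fold change 1.14, adjusted p = 4.34e-11). Of 34 squamous and keratinisation genes, 19 rose, 10 fell and 5 did not pass (19 and 11 adjusted over the list alone). The median was 0.74 and the mean -0.11 (camera adjusted p = 0.0183, adjusted p = 0.153 with an estimated correlation). The mean had the opposite sign to the median and the test. Sprr3, which encodes a cornified envelope protein, fell from 45.6 ± 1.45 to 3.30 ± 0.0128 CPM (log2 fold change -3.79, adjusted p = 2.73e-13). The keratin gene Krt6b rose from 5.77 ± 0.0751 to 42.2 ± 0.565 CPM (log2 fold change 2.87, adjusted p = 1.13e-12). Of 31 differentiated urothelial markers, 13 rose, 16 fell and 2 did not pass. The median was -0.32 and the mean -0.20 (camera adjusted p = 0.416, adjusted p = 0.798 with an estimated correlation). The test, which was upward, differed in sign from the median and mean. Of 42 S phase and mitosis genes, 31 rose, 4 fell and 7 did not pass. The median was 0.38 (camera adjusted p = 0.000262, adjusted p = 0.472 with an estimated correlation). Foxm1, a driver of mitotic genes, rose from 19.9 ± 2.44 to 63.3 ± 0.0670 CPM (log2 fold change 1.67, adjusted p = 2.19e-10). The mitotic kinase gene Aurkb rose from 21.3 ± 1.67 to 53.8 ± 2.06 CPM (log2 fold change 1.34, adjusted p = 1.01e-09).

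Of 98 developmental transcription factors, 36 passed the filter on low counts and were tested, and of these 20 rose, 10 fell and 6 did not pass (20 and 11 adjusted over the list alone). The median was 1.03 (camera adjusted p = 0.00463, adjusted p = 0.472 with an estimated correlation). Gata2, which acts in blood and urogenital development, rose from 0.238 ± 0.0374 to 12.5 ± 1.18 CPM (log2 fold change 5.70, adjusted p = 9.09e-12). Of 32 Hox genes, 19 rose, 3 fell and 10 did not pass. The median was 0.67 (camera adjusted p = 0.0079, adjusted p = 0.153 with an estimated correlation). Hoxb13, a gene of the posterior body, rose from 1.34 ± 0.00313 to 13.6 ± 1.58 CPM (log2 fold change 3.34, adjusted p = 3.25e-10). Hoxa9 rose from 63.8 ± 0.831 to 107 ± 1.38 CPM (log2 fold change 0.74, adjusted p = 1.04e-08). Of 25 neural genes, 11 passed the filter, and of these 6 rose, 1 fell and 4 did not pass. The median was 1.15 (camera adjusted p = 0.00463, adjusted p = 0.153 with an estimated correlation). Tubb3, the neuronal tubulin gene, rose from 1.07 ± 0.105 to 7.66 ± 1.295 CPM (log2 fold change 2.85, adjusted p = 3.43e-09). Of 16 WNT target genes, 7 rose, 4 fell and 5 did not pass. The median was -0.019 and the mean 1.04 (camera adjusted p = 0.0079, adjusted p = 0.153 with an estimated correlation). This median, unlike the upward mean and test, was below 0 and turned to 0.02 with RLE size factors and 0.21 with library size only. Lgr5, a stem cell receptor gene for R-spondin, had 1 count in WT DMSO and 901 in dKO DMSO, a ratio of 800 (143 to 31635), and the feedback gene Axin2 rose from 3.72 ± 0.0982 to 24.7 ± 0.0904 CPM (log2 fold change 2.73, adjusted p = 9.56e-12). The WNT target list was the only 1 of the 13 called in DMSO whose median turned with either scaling, and 0 of the lists called in the other contrasts did.

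Of 32 MAPK feedback and immediate early genes, 21 rose, 5 fell and 6 did not pass (22 and 5 adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.000748, adjusted p = 0.314 with an estimated correlation). The EGF receptor ligand gene Ereg rose from 244 ± 8.28 to 712 ± 14.3 CPM (log2 fold change 1.54, adjusted p = 6.13e-12). Dusp6, a feedback phosphatase gene, rose from 202 ± 1.62 to 442 ± 7.11 CPM (log2 fold change 1.13, adjusted p = 4.13e-11). Of 25 cholesterol genes, 18 rose, 4 fell and 3 did not pass. The median was 0.65 (camera adjusted p = 0.000126, adjusted p = 0.153 with an estimated correlation). Dhcr7, which encodes the last enzyme of cholesterol synthesis, rose from 13.0 ± 0.0856 to 45.8 ± 0.593 CPM (log2 fold change 1.81, adjusted p = 6.04e-12). Of 31 NRF2 and xenobiotic metabolism genes, 18 rose, 10 fell and 3 did not pass. The median was 0.40 (camera adjusted p = 0.0467, adjusted p = 0.748 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 186 ± 3.34 to 607 ± 29.1 CPM (log2 fold change 1.71, adjusted p = 4.38e-12). Txnrd1, a thioredoxin reductase gene, fell from 501 ± 15.8 to 208 ± 2.57 CPM (log2 fold change -1.27, adjusted p = 2e-11). Of 5 sex-chromosome genes, 3 rose, 1 fell and 1 did not pass. The median was 0.87 (camera adjusted p = 0.0352, adjusted p = 0.556 with an estimated correlation). The Y-linked genes Ddx3y (36.9 and 106 CPM) and Uty (24.0 and 43.9 CPM) were expressed in both genotypes, and Xist, the gene of X inactivation, had at most 0.353 CPM in any group.

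Lists that passed in no contrast are given for DMSO. Of 21 COMPASS-family genes, 10 rose, 6 fell and 5 did not pass (10 and 7 adjusted over the list alone). The median was 0.022 (camera adjusted p = 0.613, adjusted p = 0.807 with an estimated correlation). The test also did not pass for PRC2 genes (median -0.10, mean 0.10, camera adjusted p = 0.99), NF-kB genes (median -0.77, camera adjusted p = 0.117) or NOTCH pathway genes (median 0.61, camera adjusted p = 0.436). Nor did it for TGF-beta and BMP pathway genes (median 0.21, camera adjusted p = 0.223) or MHC class II genes (median -0.17, mean 0.74, camera adjusted p = 0.848). Endothelial markers, of which 4 were tested, had a median of -0.71 (camera adjusted p = 0.86). The immune list had 2 tested members and no test. H2-Ab1, an MHC class II gene, had 2 counts in WT DMSO and 46 in dKO DMSO, a ratio of 20.4 (5.34 to 174).

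**Figure D2:**
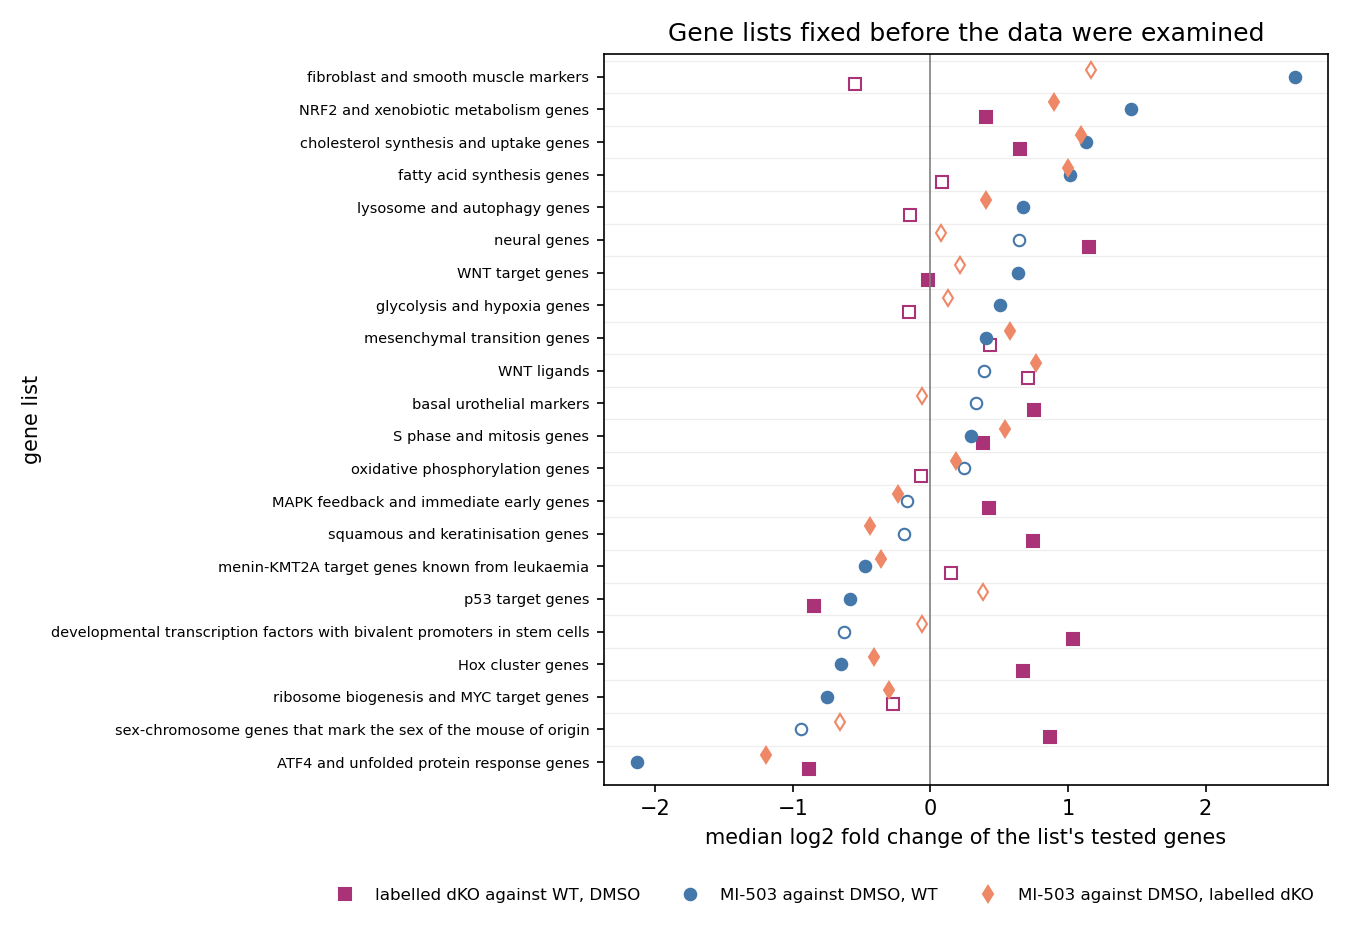
Median log2 fold change of 22 gene lists for dKO against WT in DMSO (squares) and for MI-503 against DMSO in WT (circles) and dKO (diamonds), filled where the camera adjusted p passed. ATF4 and unfolded protein response genes had medians of -0.88, -2.13 and -1.19.

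In WT cells, MI-503 was followed by a loss of RNA for protein folding, amino acid stress and ribosome production, and by a gain of RNA for detoxification, cholesterol synthesis, lipid synthesis and lysosomes. With an estimated correlation, only the call of the list of ATF4 and unfolded protein response genes held. Hspa5, which encodes the main chaperone of the ER, and Atf3, a stress-induced transcription factor, were lower. Nqo1, a quinone reductase and NRF2 target, and Scd2, which makes unsaturated fatty acids, were higher. Hox genes and the genes that menin and KMT2A are known to maintain in leukaemia, such as Meis1, were mostly lower. Some markers of smooth muscle and fibroblasts, such as the actin gene Acta2, were higher.

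Of 16921 genes, 5961 rose and 5708 fell, 2773 and 2025 by at least 2-fold, and 5252 did not pass. The split was 51.1% higher, and 60.8% with library size only, which moved the median of all genes by 0.17. Hspa5 fell from 14669 ± 801 to 342 ± 0.291 CPM (log2 fold change -5.42, adjusted p = 2.91e-15). Atf3 fell from 178 ± 0.206 to 4.60 ± 0.676 CPM (log2 fold change -5.28, adjusted p = 1.23e-14). Derl3 fell to 0.576 ± 0.0340 CPM (log2 fold change -8.54, adjusted p = 2.91e-15), and Il23a, which encodes a subunit of interleukin 23, fell from 68.5 ± 1.23 to 1.42 ± 0.00143 CPM (log2 fold change -5.59, adjusted p = 1.79e-14). Fam171b, a gene of a membrane protein of little known function, fell from 52.0 ± 4.08 to 0.485 ± 0.189 CPM (log2 fold change -6.76, adjusted p = 5.65e-13). Cavin2, which encodes a coat protein of caveolae, rose from 0.213 ± 0.00235 to 29.4 ± 0.669 CPM (log2 fold change 7.10, adjusted p = 4.69e-14). The secreted matrix protein gene Spon2 rose from 0.305 ± 0.201 to 29.6 ± 0.559 CPM (log2 fold change 6.60, adjusted p = 2.96e-12). The muscle actin gene Acta1 rose from 0.0741 ± 0.0588 to 17.5 ± 2.20 CPM (log2 fold change 7.85, adjusted p = 2.11e-11). The proliferin genes Prl2c3 and Prl2c2 rose to 55.2 ± 2.03 and 56.3 ± 3.23 CPM from 0.156 ± 0.0829 and 0.238 ± 0.0322, but these paralogs are so alike that their shares of the reads are uncertain.

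In WT, 14 of the 34 lists passed with camera, 9 upward and 5 downward, 1 with an estimated correlation, where 8 had an unadjusted p under 0.05, and 32 with fry. Of 32 ATF4 and unfolded protein response genes, 2 rose, 30 fell and 0 did not pass. The median was -2.13 (camera adjusted p = 3.41e-55, adjusted p = 0.00716 with an estimated correlation). Creld2 fell from 753 ± 16.9 to 22.7 ± 1.64 CPM (log2 fold change -5.05, adjusted p = 2.91e-15). The falls of ER chaperone RNAs in dKO DMSO and in WT MI-503 are measured from the same high WT DMSO group. Manf fell from 1184 ± 68.2 to 49.7 ± 0.345 CPM (log2 fold change -4.58, adjusted p = 3.84e-15). Of 26 p53 target genes, 5 rose, 18 fell and 3 did not pass. The median was -0.59 (camera adjusted p = 0.000166, adjusted p = 0.236 with an estimated correlation). The kinase gene Plk2 fell from 1762 ± 36.5 to 539.6 ± 10.9 CPM (log2 fold change -1.71, adjusted p = 1.2e-12). Pmaip1, a mediator of cell death, fell from 257 ± 18.9 to 62.1 ± 0.735 CPM (log2 fold change -2.05, adjusted p = 2.33e-12). Of 34 ribosome biogenesis and MYC target genes, 2 rose, 29 fell and 3 did not pass. The median was -0.75 (camera adjusted p = 8.28e-09, adjusted p = 0.191 with an estimated correlation). Wdr43 and Nop58, genes of nucleolar proteins, fell from 474 ± 0.415 to 115 ± 1.90 CPM (log2 fold change -2.05, adjusted p = 2.22e-13) and from 478 ± 4.86 to 106 ± 5.15 CPM (log2 fold change -2.17, adjusted p = 5.35e-13). Of 42 S phase and mitosis genes, 24 rose, 9 fell and 9 did not pass. The median was 0.29 (camera adjusted p = 0.0483, adjusted p = 0.609 with an estimated correlation). Aurkb rose from 21.3 ± 1.67 to 62.1 ± 1.76 CPM (log2 fold change 1.54, adjusted p = 1.56e-10).

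Of 32 Hox genes, 3 rose, 21 fell and 8 did not pass (3 and 22 adjusted over the list alone). The median was -0.65 (camera adjusted p = 0.0198, adjusted p = 0.2 with an estimated correlation). Hoxa11 fell from 47.9 ± 1.79 to 15.7 ± 0.0541 CPM (log2 fold change -1.61, adjusted p = 2.67e-11). Of 17 menin and KMT2A target genes known from leukaemia, 3 rose, 10 fell and 4 did not pass. The median was -0.48 (camera adjusted p = 0.041, adjusted p = 0.204 with an estimated correlation). The Hoxa members of this list, such as Hoxa9 and Hoxa11, are also in the Hox list, so these lists are not separate evidence. Meis1, a partner of Hox proteins, fell from 34.8 ± 1.31 to 11.9 ± 0.203 CPM (log2 fold change -1.55, adjusted p = 1.93e-10). Jmjd1c, a demethylase-family gene, fell from 215 ± 8.59 to 99.3 ± 2.19 CPM (log2 fold change -1.12, adjusted p = 2.2e-10). Of 16 WNT target genes, 10 rose, 4 fell and 2 did not pass. The median was 0.64 (camera adjusted p = 0.0198, adjusted p = 0.2 with an estimated correlation). Axin2 rose from 3.72 ± 0.0982 to 11.5 ± 0.757 CPM (log2 fold change 1.63, adjusted p = 1.55e-09). Lgr6, a receptor gene for R-spondin, rose from 1.05 ± 0.151 to 47.4 ± 0.158 CPM (log2 fold change 5.49, adjusted p = 1.09e-13).

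Of 31 NRF2 and xenobiotic metabolism genes, 26 rose, 4 fell and 1 did not pass. The median was 1.46 (camera adjusted p = 1.02e-14, adjusted p = 0.2 with an estimated correlation). Nqo1 rose from 20.1 ± 1.82 to 219.6 ± 8.14 CPM (log2 fold change 3.45, adjusted p = 1.09e-13). The carbonyl reductase gene Cbr3 rose from 1.304 ± 0.0204 to 40.2 ± 0.575 CPM (log2 fold change 4.94, adjusted p = 1.98e-13). Of 25 cholesterol genes, 23 rose, 1 fell and 1 did not pass (23 and 2 adjusted over the list alone). The median was 1.13 (camera adjusted p = 1.21e-13, adjusted p = 0.05 with an estimated correlation). Dhcr7 rose from 13.0 ± 0.0856 to 75.8 ± 1.54 CPM (log2 fold change 2.54, adjusted p = 2.58e-13). Of 14 fatty acid synthesis genes, 11 rose, 2 fell and 1 did not pass (12 and 2 adjusted over the list alone). The median was 1.02 (camera adjusted p = 1.34e-08, adjusted p = 0.2 with an estimated correlation). Scd2 rose from 310.2 ± 2.85 to 2703 ± 19.3 CPM (log2 fold change 3.12, adjusted p = 1.78e-14). Acss2, an acetyl-CoA synthetase gene, rose from 8.18 ± 0.00891 to 47.4 ± 1.42 CPM (log2 fold change 2.53, adjusted p = 2.27e-12). Of 30 lysosome and autophagy genes, 21 rose, 8 fell and 1 did not pass. The median was 0.67 (camera adjusted p = 5.62e-05, adjusted p = 0.2 with an estimated correlation). Gpnmb, a lysosomal stress marker, rose from 78.6 ± 5.34 to 1172 ± 21.6 CPM (log2 fold change 3.90, adjusted p = 1.24e-14). The autophagy receptor gene Sqstm1 fell from 850.2 ± 1.90 to 307 ± 7.34 CPM (log2 fold change -1.47, adjusted p = 4.58e-12). Of 35 identifiers of glycolysis and hypoxia genes, which stand for 34 symbols because Aldoa has 2, 22 rose, 9 fell and 4 did not pass. The median was 0.51 (camera adjusted p = 0.0349, adjusted p = 0.609 with an estimated correlation). The hexokinase gene Hk1 rose from 73.5 ± 3.84 to 324 ± 14.2 CPM (log2 fold change 2.14, adjusted p = 4.2e-12). Ndrg1, a hypoxia marker, fell from 297 ± 0.234 to 74.0 ± 5.51 CPM (log2 fold change -2.0024, adjusted p = 4.41e-12).

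Of 23 mesenchymal transition genes, 10 rose, 7 fell and 6 did not pass. The median was 0.40 (camera adjusted p = 0.0349, adjusted p = 0.429 with an estimated correlation). The YAP target gene Ccn2 rose from 36.8 ± 0.987 to 305 ± 5.59 CPM (log2 fold change 3.05, adjusted p = 1.79e-14). Tgfbi, a matrix gene, rose from 29.5 ± 2.10 to 249 ± 2.37 CPM (log2 fold change 3.08, adjusted p = 8.38e-14). Of 19 fibroblast and smooth muscle markers, 8 passed the filter, and of these 4 rose, 1 fell and 3 did not pass. The median was 2.65 (camera adjusted p = 0.0246, adjusted p = 0.2 with an estimated correlation). The smooth muscle actin gene Acta2 rose from 3.20 ± 0.615 to 40.8 ± 1.68 CPM (log2 fold change 3.67, adjusted p = 5.1e-12). The matrix gene Fbln1 rose from 3.12 ± 0.998 to 46.9 ± 2.09 CPM (log2 fold change 3.91, adjusted p = 2.54e-11). Collagen gene Col1a1 stayed at 0.0163 and 0.0689 CPM, the fibroblast gene Dcn had 0 counts in all 8 libraries, and the immune marker Ptprc had 0 counts in WT DMSO and 2 in WT MI-503. Among other immune markers below the filter, Itgam went from 4 to 20 counts, Csf1r from 1 to 9 and Laptm5 from 7 to 16. Fcer1g went from 7 to 1 and Cd3e from 2 to 1. Cd68 and Cd14, genes of macrophages, lysosomes and some epithelia, rose from 17.5 ± 1.51 to 163 ± 4.12 CPM (log2 fold change 3.22, adjusted p = 4.65e-13) and from 9.40 ± 0.685 to 45.3 ± 1.77 CPM (log2 fold change 2.27, adjusted p = 8.63e-12). The endothelial marker Pecam1 had 9 counts in WT DMSO and 7 in WT MI-503.

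In cells labelled dKO, MI-503 was followed by a loss of amino acid stress RNA and a gain of cholesterol, lipid, detoxification and proliferation RNA. With an estimated correlation, only the calls of ATF4 and unfolded protein response genes and of cholesterol genes held. Trib3, a pseudokinase induced by ATF4, and Atf3 were among the genes with the steepest losses, together with Ppp1r15a, which ends the stress block of translation. Cavin2 and the R-spondin receptor gene Lgr6 were among those with the largest gains. The EGF receptor ligand genes Ereg and Areg were lower. Hox genes were mostly lower, as in WT.

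Of 16921 genes, 4917 rose and 4485 fell, 1504 and 879 by at least 2-fold, and 7519 did not pass. The split was 52.3% higher. Trib3 fell from 294 ± 31.9 to 16.8 ± 2.42 CPM (log2 fold change -4.13, adjusted p = 9.46e-12), Atf3 from 77.6 ± 0.207 to 4.38 ± 0.0451 CPM (log2 fold change -4.15, adjusted p = 3.78e-13). Ppp1r15a fell from 279 ± 13.9 to 14.2 ± 1.43 CPM (log2 fold change -4.30, adjusted p = 1.21e-13). Acot2, a mitochondrial acyl-CoA thioesterase gene, fell from 25.7 ± 1.36 to 1.28 ± 0.205 CPM (log2 fold change -4.32, adjusted p = 6.6e-12). The cytokine gene Tnfsf15 fell from 35.0 ± 0.325 to 1.26 ± 0.316 CPM (log2 fold change -4.78, adjusted p = 2.44e-12). Cavin2 rose from 0.540 ± 0.0299 to 19.96 ± 0.575 CPM (log2 fold change 5.21, adjusted p = 8.44e-13), Lgr6 from 0.929 ± 0.144 to 12.1 ± 0.368 CPM (log2 fold change 3.70, adjusted p = 1.96e-11). The imprinted gene Mest rose from 1.71 ± 0.476 to 19.4 ± 1.23 CPM (log2 fold change 3.51, adjusted p = 1.01e-09). Lpin1, which encodes a phosphatase of lipid synthesis, rose from 5.75 ± 0.401 to 70.02 ± 1.88 CPM (log2 fold change 3.61, adjusted p = 3.97e-13). Prl2c3 rose to 35.3 ± 2.02 CPM, with the same doubt about its paralogs.

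In labelled dKO cells, 14 of the 34 lists passed with camera, 8 upward and 6 downward, 2 with an estimated correlation, where 9 had an unadjusted p under 0.05, and 27 with fry. Of 32 ATF4 and unfolded protein response genes, 1 rose, 30 fell and 1 did not pass. The median was -1.19 (camera adjusted p = 1.05e-50, adjusted p = 0.00553 with an estimated correlation). Aldh1l2, a mitochondrial folate enzyme gene, fell from 356 ± 6.15 to 40.5 ± 1.86 CPM (log2 fold change -3.14, adjusted p = 1.21e-13). Of 26 p53 target genes, 17 rose, 9 fell and 0 did not pass. The median was 0.38 (camera adjusted p = 0.0533, adjusted p = 0.497 with an estimated correlation), and this list did not pass. Of 34 ribosome biogenesis and MYC target genes, 5 rose, 22 fell and 7 did not pass. The median was -0.30 (camera adjusted p = 2.72e-05, adjusted p = 0.185 with an estimated correlation). Wdr43 fell from 316 ± 7.13 to 132 ± 0.126 CPM (log2 fold change -1.26, adjusted p = 5.07e-11). Nop56, another nucleolar gene, fell from 366 ± 8.69 to 189 ± 4.98 CPM (log2 fold change -0.96, adjusted p = 8.98e-10). Of 42 S phase and mitosis genes, 37 rose, 2 fell and 3 did not pass. The median was 0.54 (camera adjusted p = 2.19e-11, adjusted p = 0.185 with an estimated correlation). Cdc20, which acts at the exit from mitosis, rose from 63.9 ± 2.06 to 149 ± 2.61 CPM (log2 fold change 1.22, adjusted p = 3.25e-10). The mitotic kinase gene Cdk1 rose from 114 ± 7.16 to 236 ± 4.64 CPM (log2 fold change 1.05, adjusted p = 1.35e-09). Of 32 MAPK feedback and immediate early genes, 7 rose, 16 fell and 9 did not pass. The median was -0.24 (camera adjusted p = 3.47e-05, adjusted p = 0.185 with an estimated correlation). Ereg fell from 712 ± 14.3 to 174 ± 6.66 CPM (log2 fold change -2.03, adjusted p = 2.25e-12). Areg fell from 509 ± 9.68 to 136 ± 5.05 CPM (log2 fold change -1.91, adjusted p = 3.92e-12).

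Of 25 cholesterol genes, 24 rose, 0 fell and 1 did not pass. The median was 1.09 (camera adjusted p = 5.36e-25, adjusted p = 0.0162 with an estimated correlation). Insig1, a sterol sensor gene, rose from 14.4 ± 1.67 to 75.1 ± 3.07 CPM (log2 fold change 2.38, adjusted p = 2.9e-11). The sterol carrier gene Stard4 rose from 57.1 ± 1.25 to 141 ± 4.02 CPM (log2 fold change 1.3006, adjusted p = 1.21e-10). Of 14 fatty acid synthesis genes, 12 rose, 1 fell and 1 did not pass. The median was 0.9976 (camera adjusted p = 4.21e-16, adjusted p = 0.114 with an estimated correlation). Scd2 rose from 614 ± 26.4 to 3400.2 ± 2.93 CPM (log2 fold change 2.47, adjusted p = 4.47e-13). The desaturase gene Fads2 rose from 75.5 ± 0.931 to 266 ± 3.45 CPM (log2 fold change 1.82, adjusted p = 6.85e-12). Of 31 NRF2 and xenobiotic metabolism genes, 22 rose, 5 fell and 4 did not pass (23 and 5 adjusted over the list alone). The median was 0.90 (camera adjusted p = 7.98e-19, adjusted p = 0.185 with an estimated correlation). Gclc, which starts glutathione synthesis, rose from 132 ± 7.97 to 591 ± 23.7 CPM (log2 fold change 2.16, adjusted p = 5.95e-12). Nqo1 rose from 26.6 ± 1.56 to 141 ± 4.42 CPM (log2 fold change 2.41, adjusted p = 6.76e-12). Of 30 lysosome and autophagy genes, 20 rose, 3 fell and 7 did not pass. The median was 0.40 (camera adjusted p = 6.78e-05, adjusted p = 0.185 with an estimated correlation). Gpnmb rose from 64.3 ± 1.003 to 462 ± 20.3 CPM (log2 fold change 2.84, adjusted p = 4.47e-13). Of 37 oxidative phosphorylation genes, 20 rose, 2 fell and 15 did not pass. The median was 0.18 (camera adjusted p = 0.00585, adjusted p = 0.223 with an estimated correlation). Ndufb3, a complex I subunit gene, rose from 30.7 ± 1.78 to 55.7 ± 2.60 CPM (log2 fold change 0.86, adjusted p = 4.63e-08).

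Of 32 Hox genes, 0 rose, 18 fell and 14 did not pass. The median was -0.41, or -0.39 with genes at 0 counts set to the floor (camera adjusted p = 0.0235, adjusted p = 0.185 with an estimated correlation). Hoxb9 fell from 8.54 ± 1.17 to 2.33 ± 0.151 CPM (log2 fold change -1.87, adjusted p = 3.6e-08). Hoxa9 fell from 107 ± 1.38 to 73.8 ± 0.562 CPM (log2 fold change -0.53, adjusted p = 5.08e-07). Of 17 menin and KMT2A target genes, 2 rose, 11 fell and 4 did not pass. The median was -0.36 (camera adjusted p = 0.0329, adjusted p = 0.185 with an estimated correlation). Here too, the Hoxa members are shared with the Hox list. Meis1 fell from 30.1 ± 0.938 to 10.9 ± 0.632 CPM (log2 fold change -1.47, adjusted p = 1.22e-09). Of 34 squamous and keratinisation genes, 7 rose, 14 fell and 13 did not pass. The median was -0.44 (camera adjusted p = 0.0235, adjusted p = 0.185 with an estimated correlation). The desmosomal cadherin gene Dsc3 fell from 139.7 ± 4.68 to 45.0 ± 1.72 CPM (log2 fold change -1.63, adjusted p = 5.8e-11). Krt6b fell from 42.2 ± 0.565 to 10.5 ± 0.168 CPM (log2 fold change -2.01, adjusted p = 5.84e-11).

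Of 15 WNT ligand genes, 9 passed the filter, and of these 7 rose, 1 fell and 1 did not pass. The median was 0.77 (camera adjusted p = 0.0235, adjusted p = 0.501 with an estimated correlation). Wnt7a rose from 6.33 ± 1.26 to 24.7 ± 0.586 CPM (log2 fold change 1.96, adjusted p = 1.76e-09). Wnt7b fell from 209 ± 12.3 to 129 ± 6.10 CPM (log2 fold change -0.70, adjusted p = 3.55e-07). Of 23 mesenchymal transition genes, 13 rose, 6 fell and 4 did not pass (14 and 6 adjusted over the list alone). The median was 0.58 (camera adjusted p = 0.00286, adjusted p = 0.223 with an estimated correlation). Ccn2 rose from 23.6 ± 0.482 to 147 ± 3.59 CPM (log2 fold change 2.64, adjusted p = 3.78e-13). Snai2, a repressor of epithelial genes, fell from 318 ± 11.5 to 77.2 ± 0.460 CPM (log2 fold change -2.04, adjusted p = 2.1e-12). Among markers of other cell types, Acta2 rose from 0.988 ± 0.168 to 7.14 ± 0.0173 CPM (log2 fold change 2.86, adjusted p = 1.84e-09). Fbln1 rose from 4.35 ± 0.107 to 12.1 ± 1.48 CPM (log2 fold change 1.48, adjusted p = 9.2e-07) and Cd68 rose from 13.1 ± 0.0175 to 65.5 ± 6.13 CPM (log2 fold change 2.32, adjusted p = 2.93e-11). Ptprc had 1 count in each group labelled dKO, and Pecam1 had 8 counts in dKO DMSO and 7 in dKO MI-503.

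MI-503 was followed by less RNA of most unfolded protein response and ribosome production genes in WT, and many of them fell less in labelled dKO cells. For ER chaperone genes, the fall in WT and this difference are both measured from the high WT DMSO group. No test here separates them from the culture state of that group. More p53 target genes fell than rose in WT, and more rose than fell in labelled dKO cells, where the list did not pass. Between the genotypes in MI-503 the p53 list had a median of 0.12 and did not pass. The fall of p53 targets in WT and their difference are also measured from the WT DMSO group. Its culture state is not separated from them either. Most unfolded protein response and p53 target RNAs were already lower in dKO DMSO. Derl3, the folding factor genes Creld2 and Sdf2l1, and the inducible heat-shock genes Hspa1b and Hsph1 had the most positive differences. Proliferin genes, the lipoxygenase gene Alox15 and the potassium channel gene Kcnq1 had the most negative. Both rankings cover called genes with a proper symbol and a mean of at least 5 CPM over all libraries, which Derl3 reached through WT DMSO. Most basal markers and glycolysis genes, and many interferon response genes, had a more negative effect in labelled dKO cells, though none of the list calls of this contrast held with an estimated correlation.

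The interaction passed with a more positive effect in labelled dKO cells for 4190 genes and a more negative one for 3725, of which 930 and 1127 differed by at least 2-fold, and 9006 did not pass. The split was 52.9% positive, but 49.8% with RLE size factors, 49.9% with DESeq2, 42.7% with no filter and 37.2% with library size only, which moved the median of all genes by -0.16. The log2 effect of MI-503 on Derl3 was -8.54 in WT and -1.36 in labelled dKO cells (difference 7.18, adjusted p = 1.45e-08), and that on Creld2 was -5.05 in WT and -0.59 in labelled dKO cells (difference 4.46, adjusted p = 8.44e-13). Derl3 was already far lower in dKO DMSO than in WT DMSO, which limits how far it could fall there. For Hspa1b the effect was -4.76 in WT and -0.20 in labelled dKO cells (difference 4.57, adjusted p = 4.68e-11), and for Hsph1 it was -4.14 in WT and -0.049 in labelled dKO cells (difference 4.10, adjusted p = 6.15e-12). The effect on Alox15 was 5.23 in WT and 0.85 in labelled dKO cells (difference -4.37, adjusted p = 3.37e-06) and that on Kcnq1 was 3.96 in WT and -0.15 in labelled dKO cells (difference -4.10, adjusted p = 1.39e-10). Kmt2a had a less negative effect in labelled dKO cells (difference 0.28, adjusted p = 0.00414) and Men1 a less positive one (-0.51, adjusted p = 0.00317). The call of Kmt2a ended with library size only (0.12) and with no filter (0.18).

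For the interaction, 13 of the 34 lists passed with camera, 6 upward and 7 downward, 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 24 with fry. Of 32 ATF4 and unfolded protein response genes, 16 had a more positive effect, 9 a more negative effect and 7 did not pass (16 and 10 adjusted over the list alone). The median was 0.23 (camera adjusted p = 7.91e-21, adjusted p = 0.0642 with an estimated correlation). In the lists chosen after values were seen, all 22 ER chaperone genes had a more positive effect (median 2.67). Of 22 ATF4 targets, 6 had a more positive and 11 a more negative effect (median -0.19). The effect on Manf was -4.58 in WT and -0.50 in labelled dKO cells (difference 4.07, adjusted p = 8.44e-13). Of 26 p53 target genes, 17 had a more positive effect, 2 a more negative effect and 7 did not pass. The median was 0.92 (camera adjusted p = 2.23e-15, adjusted p = 0.164 with an estimated correlation). The effect on Cdkn1a was -1.34 in WT and 0.51 in labelled dKO cells (difference 1.85, adjusted p = 3.62e-10). Of 34 ribosome biogenesis and MYC target genes, 22 had a more positive effect, 5 a more negative effect and 7 did not pass (23 and 5 adjusted over the list alone). The median was 0.43 (camera adjusted p = 4.61e-05, adjusted p = 0.314 with an estimated correlation). The mitochondrial chaperone gene Hspd1 had effects of -1.9995 in WT and 0.0010 in labelled dKO cells (difference 2.0005, adjusted p = 2.06e-09). Of 16 MHC class I genes, 6 had a more positive effect, 3 a more negative effect and 7 did not pass. The median was 0.26 (camera adjusted p = 0.00308, adjusted p = 0.335 with an estimated correlation). The loading factor gene Calr, also an ER chaperone gene, had effects of -2.74 in WT and 0.48 in labelled dKO cells (difference 3.22, adjusted p = 4.28e-12). Of 42 S phase and mitosis genes, 21 had a more positive effect, 7 a more negative effect and 14 did not pass (23 and 7 adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.00688, adjusted p = 0.505 with an estimated correlation). The replication licensing gene Cdc6 had effects of -1.24 in WT and 0.27 in labelled dKO cells (difference 1.51, adjusted p = 6.05e-08). Of 8 cyclin-dependent kinase inhibitor genes, 4 had a more positive effect, 2 a more negative effect and 2 did not pass. The median was 0.39 (camera adjusted p = 0.0454, adjusted p = 0.431 with an estimated correlation).

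Of 21 basal markers, 2 had a more positive effect, 15 a more negative effect and 4 did not pass. The median was -0.70 (camera adjusted p = 0.000265, adjusted p = 0.416 with an estimated correlation). The effect on Itga6 was 0.38 in WT and -0.76 in labelled dKO cells (difference -1.14, adjusted p = 1.79e-08). Of 28 epithelial junction genes, 2 had a more positive effect, 16 a more negative effect and 10 did not pass. The median was -0.33 (camera adjusted p = 0.00549, adjusted p = 0.416 with an estimated correlation). The E-cadherin gene Cdh1 had effects of 0.22 in WT and -0.81 in labelled dKO cells (difference -1.03, adjusted p = 1.93e-08). Of 34 squamous genes, 5 had a more positive effect, 13 a more negative effect and 16 did not pass. The median was -0.44 (camera adjusted p = 0.0132, adjusted p = 0.314 with an estimated correlation). Of the 35 identifiers of glycolysis and hypoxia genes, 6 had a more positive effect, 22 a more negative effect and 7 did not pass. The median was -0.46 (camera adjusted p = 0.000303, adjusted p = 0.444 with an estimated correlation). Hk1 had effects of 2.14 in WT and 0.73 in labelled dKO cells (difference -1.41, adjusted p = 4.1e-08). Of 32 interferon response genes, 1 had a more positive effect, 15 a more negative effect and 16 did not pass (1 and 16 adjusted over the list alone). The median was -1.05 (camera adjusted p = 0.0064, adjusted p = 0.505 with an estimated correlation). The antiviral gene Oas3 had effects of 4.39 in WT and 0.43 in labelled dKO cells (difference -3.96, adjusted p = 1.06e-06). Of 31 NRF2 genes, 6 had a more positive effect, 19 a more negative effect and 6 did not pass (6 and 20 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0026, adjusted p = 0.505 with an estimated correlation). Of 30 lysosome genes, 7 had a more positive effect, 13 a more negative effect and 10 did not pass. The median was -0.21 (camera adjusted p = 0.0369, adjusted p = 0.499 with an estimated correlation).

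**Figure D3:**
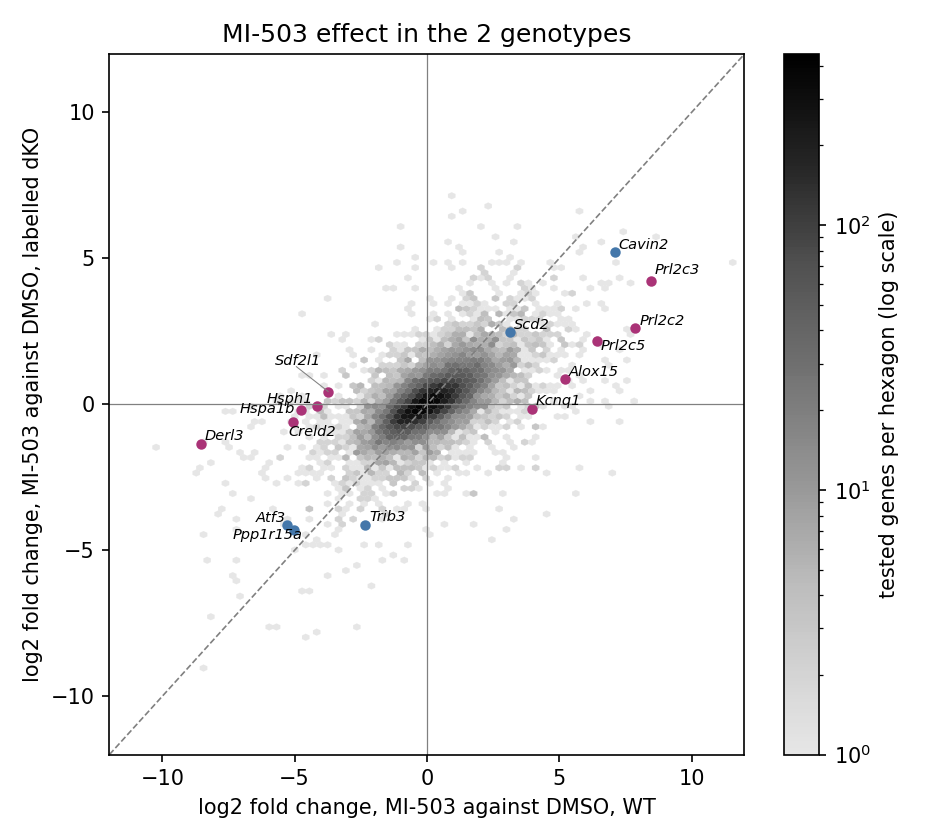
Log2 fold change with MI-503 in WT (x axis) and in labelled dKO cells (y axis) for the genes tested, shaded by the number of genes, with the line of equal effects dashed. The 10 genes named for the interaction, 5 in each direction, are purple, and Cavin2, Scd2, Trib3, Atf3 and Ppp1r15a are blue.

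MI-503 moved many genes the same way in both genotypes, among them Scd2, Cavin2, Atf3 and the 15 Hox genes called in both. Genes that differed between the genotypes in DMSO mostly differed likewise in MI-503. Genes raised in labelled dKO cells were not generally lowered by MI-503, although Epgn, an EGF receptor ligand gene, and Zeb2, a regulator of mesenchymal transition, were. The matrix genes Sparc and Col8a1 went from low in labelled dKO cells to higher with MI-503.

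Across the 16921 genes, which are not independent replicates, the MI-503 effects in WT and labelled dKO cells had a correlation of 0.61. Of 7871 genes called in both, 7015 (89.1%) moved the same way and 856 the opposite way. Of the genes called the same way, 3837 also passed the interaction and 3178 did not. The genotype effects in DMSO and MI-503, which share no libraries, had a correlation of 0.73, and 6024 of 7340 genes called in both (82.1%) moved the same way. The genotype effect in DMSO and the MI-503 effect in labelled dKO cells share the dKO DMSO libraries with opposite sign. Their correlation was -0.12, against -0.48 simulated for unchanged groups, and their covariance -0.161 against -0.0349. Fold changes of unchanged groups vary far less, so the covariances can be compared and the correlations cannot. The inverse covariance was larger than sharing alone gave, by -0.126, although the counts of calls below show no excess of genes that rose and then fell. With a different dKO DMSO library in each contrast, the correlation was -0.05 and -0.03. These values were taken from differences of log2 CPM and not from fitted fold changes. The change from -0.12 can therefore not be put down to the sharing alone. In those contrasts, 1296 genes rose in labelled dKO cells and fell with MI-503, against 1330 if the calls were independent, and 1872 fell and then rose, against 1759, while 1816 rose in both (1458 independent) and 2125 fell in both (1604). The genotype effect in DMSO and the MI-503 effect in WT share the WT DMSO libraries and had a correlation of 0.22, against 0.52 simulated, and a covariance of 0.423 against 0.0379. This correlation too cannot be compared with its simulated value, and the covariance was larger than sharing alone gave.

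Among genes that rose in labelled dKO cells and fell with MI-503, Epgn rose from 49.8 ± 0.113 to 239 ± 13.4 CPM (log2 fold change 2.26, adjusted p = 6.11e-13) and then fell to 20.04 ± 0.701 CPM (-3.58, adjusted p = 1.21e-13), and Zeb2 rose from 1.72 ± 0.213 to 15.7 ± 0.705 CPM (log2 fold change 3.19, adjusted p = 2.09e-10) and then fell to 3.45 ± 0.653 (-2.19, adjusted p = 6.89e-09). The others named by the rule were Prune2, Klf12 and Krt6b. In the other direction, Sparc fell from 117 ± 7.53 to 0.674 ± 0.117 CPM (log2 fold change -7.42, adjusted p = 5.19e-15) and then rose to 3.82 ± 0.304 (2.49, adjusted p = 3.95e-09), and Col8a1 fell from 60.9 ± 0.683 to 0.478 ± 0.160 CPM (log2 fold change -7.00, adjusted p = 1.4e-14) and then rose to 3.26 ± 0.203 (2.78, adjusted p = 5.11e-09). The others were Plekha6, Trp53i11 and Arhgdib.

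In MI-503, labelled dKO cells had more RNA of the tested proliferation, Hox, developmental and neural genes than WT cells, and less RNA of epithelial junction and lysosome genes, though none of these list calls held with an estimated correlation. Of 16921 genes, 4494 rose and 4828 fell, 1111 and 1802 by at least 2-fold, and 7599 did not pass. Of the calls, 48.2% were higher, against 56.2% with library size only and 57.0% with the stricter filter. In this contrast 12 lists passed with camera, 9 upward and 3 downward, 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 28 with fry. Of 42 S phase and mitosis genes, 38 rose, 2 fell and 2 did not pass. The median was 0.68 (camera adjusted p = 1.85e-13, adjusted p = 0.242 with an estimated correlation). Of 32 Hox genes, 23 rose, 3 fell and 6 did not pass. The median was 0.96 (camera adjusted p = 9.1e-06, adjusted p = 0.156 with an estimated correlation). Of 28 epithelial junction genes, 2 rose, 21 fell and 5 did not pass (2 and 22 adjusted over the list alone). The median was -0.70 (camera adjusted p = 9.1e-06, adjusted p = 0.242 with an estimated correlation). Of the 36 developmental transcription factors tested, 23 rose, 9 fell and 4 did not pass. The median was 1.39 (camera adjusted p = 2.62e-05, adjusted p = 0.317 with an estimated correlation). Of the 11 neural genes tested, 7 rose, 1 fell and 3 did not pass. The median was 1.84 (camera adjusted p = 9.36e-05, adjusted p = 0.176 with an estimated correlation). Of 25 cholesterol genes, 21 rose, 3 fell and 1 did not pass. The median was 0.36 (camera adjusted p = 0.000416, adjusted p = 0.242 with an estimated correlation). Of 30 lysosome genes, 4 rose, 19 fell and 7 did not pass. The median was -0.25 (camera adjusted p = 0.000339, adjusted p = 0.317 with an estimated correlation).

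Of the 35 glycolysis and hypoxia identifiers in MI-503, 9 rose, 21 fell and 5 did not pass (9 and 23 adjusted over the list alone). The median was -0.35 (camera adjusted p = 0.0149, adjusted p = 0.518 with an estimated correlation). Of 32 MAPK feedback genes, 16 rose, 8 fell and 8 did not pass (17 and 9 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.0149, adjusted p = 0.355 with an estimated correlation). Of 34 ribosome biogenesis and MYC target genes, 18 rose, 4 fell and 12 did not pass. The median was 0.19 (camera adjusted p = 0.0301, adjusted p = 0.355 with an estimated correlation). Of 21 basal markers, 11 rose, 4 fell and 6 did not pass (12 and 4 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.0301, adjusted p = 0.475 with an estimated correlation). Of 5 sex-chromosome genes, 3 rose, 1 fell and 1 did not pass. The median was 1.31 (camera adjusted p = 0.00797, adjusted p = 0.355 with an estimated correlation). Acta2 and Fbln1, markers of other cell types, were at 40.8 ± 1.68 and 46.9 ± 2.09 CPM in WT MI-503 and at 7.14 ± 0.0173 and 12.1 ± 1.48 in dKO MI-503.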

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

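The tests of a single aberrant library and of scaling, and the lists of ER chaperone and cytosolic heat-shock genes, were chosen after the result was seen.

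A difference between the genotypes in the MI-503 effect, tested with the edgeR interaction, singled out 4190 genes with a more positive and 3725 with a more negative effect in labelled dKO cells. Among the named genes the difference in log2 effect was positive for Derl3 (7.18), Hspa1b (4.57), Creld2 (4.46), Sdf2l1 (4.17), Hsph1 (4.10), Manf (4.07), Calr (3.22), Pdia3 (2.60), Hspd1 (2.00) and Hspe1 (1.77), which act in protein folding. It was also positive for Cdkn1a (1.85), Btg2 (1.82) and Plk2 (1.44), targets of p53, for the replication gene Cdc6 (1.51) and for Kmt2a (0.28). It was negative for the proliferin genes Prl2c2 (-5.27), Prl2c5 (-4.25) and Prl2c3 (-4.22), for Alox15 (-4.37), Kcnq1 (-4.10) and the antiviral gene Oas3 (-3.96). It was negative as well for Hk1 (-1.41), for Itga6 (-1.14), Cdh1 (-1.03) and Lama3 (-0.70), genes of cell adhesion, and for Men1 (-0.51).

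Among the lists, the median difference was 0.23 for ATF4 and unfolded protein response genes, 0.92 for p53 targets, 0.43 for ribosome biogenesis genes, 0.28 for S phase genes, 0.26 for MHC class I genes and 0.39 for cyclin-dependent kinase inhibitors. It was -0.70 for basal markers, -0.44 for squamous genes, -0.33 for junction genes, -0.46 for glycolysis genes, -0.40 for NRF2 genes, -0.21 for lysosome genes and -1.05 for interferon genes. These lists passed with camera at the preset correlation and 0 of them with an estimated correlation, where the lowest adjusted p was 0.0642.

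The pattern weighed here is that ER chaperone and heat-shock RNAs were highest in WT DMSO. For 37 of the 37 members, the lower WT DMSO library lay above the other 6 libraries, which argues against a single aberrant library. With library size only, the median log2 fold change of the members in dKO against WT in DMSO was still -2.07, which argues against scaling by TMM factors. This outcome followed from the size of the factors, since leaving them out moved the median of all genes by only 0.23. Stress of the WT DMSO cultures at harvest was not tested and stays open, since the labels do not record the state of the cultures. A genotype effect alone does not give this pattern, since these RNAs were also low in WT MI-503, with heat-shock genes at 1.152% and 1.201% of TMM-scaled counts against 2.55% and 2.78% in WT DMSO, and ER chaperone genes at 0.458% and 0.465%. A genotype effect in DMSO together with a fall with MI-503 in WT is the biological explanation the design offers. It may hold as well, but no test here separates it from culture state.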

How the results depend on the processing

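The medians of the gene lists with library size only were chosen after the result was seen, as were the further thresholds for all-or-none expression. The alternative by chromosome with unresponsive genes only was added after the data were examined, but before its own result was seen. All 12 counts of called genes stayed within 1.5 times their value under the alternatives run, although the share of higher calls moved with library size only, with no filter, with the stricter filter and, for dKO against WT in DMSO, with only the groups compared. Of 3787 values of 257 results for named genes under the alternatives, 3767 kept their direction and their side of the threshold, 8 kept only the direction, 1 passed in addition and 11 reversed, all in Kmt2a, Kmt2c or Kmt2d. Apart from Kmt2c, Kmt2d, Kmt2a and Men1, the rule took only called genes with the largest changes or the smallest adjusted p in these data. That such genes kept their calls was therefore largely fixed in advance and says little about other genes. With library size only, 21 calls in dKO against WT in DMSO turned direction.

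With an estimated correlation, 0, 1, 2, 0 and 0 lists passed for dKO against WT in DMSO, MI-503 in WT, MI-503 in dKO, the interaction and dKO against WT in MI-503, and with fry 24, 32, 27, 24 and 28. Of the 66 list calls, 63 ended with an estimated correlation. In dKO against WT in DMSO, this correlation was -0.0017 for Hox, -0.013 for squamous, -0.060 for WNT target and -0.080 for neural genes. These values lie below the preset 0.01, which argues against a higher correlation between members as the cause for these lists. The other lists called there lay above it, from 0.030 to 0.56. Camera with an estimated correlation also takes its p on the 4 residual degrees of freedom, which alone raises it. For Hox genes its unadjusted p was 0.0252, against 0.00232 with the preset correlation. How much the correlation and the degrees of freedom each added in the other lists was not tested. RLE size factors ended 1 list call, cyclin-dependent kinase inhibitors in the interaction (adjusted p = 0.0502). With library size only, called medians of the interaction moved without turning. The median went from 0.23 to 0.073 for ATF4 and unfolded protein response genes, from 0.28 to 0.12 for S phase genes and from -0.21 to -0.37 for lysosome genes.

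The Kmt2d interaction, near 0 and not called, reversed to -0.029 with RLE size factors, -0.16 with library size only, -0.031 with DESeq2, -0.097 with no filter and -0.017 with the stricter filter, and ran from -0.14 to 0.14 without 1 library. The Kmt2c interaction passed with library size only (-0.23) and ran from -0.15 to 0.0078 without 1 library. The calls of Kmt2d with MI-503 in WT ended with library size only (-0.19) and DESeq2 (-0.33). The cause was not tested.

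Replicates share only a number: the deviations of equal numbers had correlations of -0.066 to 0.058 across groups, so the numbers pair nothing and the block is no measure of a weaker effect. With the replicate block, the Kmt2d interaction was -0.0040, and 2 list calls ended, NRF2 genes in dKO against WT in DMSO (adjusted p = 0.0592) and S phase genes with MI-503 in WT (0.0521). Depth limits genes near the floor of 3 counts, and the 2 libraries per group limit small changes. In simulated data with few changed genes, 20% of 1.3-fold interactions were recovered, a share that does not carry over to these data.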

Other observations

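The tests by chromosome and of genes with all-or-none expression were chosen after the result was seen, except that of MI-503 responsive genes by chromosome.

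ATF4 target genes did not move with ER chaperone and cytosolic heat-shock genes in every contrast, and these 3 lists were chosen after values were seen. In dKO against WT in DMSO, 22 of 22 ER chaperone genes fell (median -2.60) and so did 15 of 15 heat-shock genes (-2.01), whereas 11 of 22 ATF4 targets rose and 9 fell. With MI-503 in WT, all 22 ER chaperone genes (-2.80), all 15 heat-shock genes (-1.96) and 19 ATF4 targets fell. With MI-503 in labelled dKO cells, all 22 ATF4 targets fell (-1.54), while the ER chaperone genes had a median of -0.28, with 5 risen and 13 fallen, and the heat-shock genes 0.073. Between the genotypes in MI-503, the ER chaperone genes had a median of 0.031, with 7 risen and 8 fallen. The heat-shock genes had a median of -0.035, with 2 risen and 6 fallen, and the ATF4 targets -0.40, with 2 risen and 13 fallen. The ATF4 list shares members with the fixed list of ATF4 and unfolded protein response genes.

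Among differentiated markers, the uroplakin gene Upk1b stayed near 138 CPM in WT DMSO and 140.5 in dKO DMSO. The nuclear receptor gene Pparg, a driver of urothelial differentiation, was at 20.8 ± 0.0960 and 8.002 ± 0.691 CPM, the umbrella cell keratin gene Krt20 at 0.320 ± 0.0847 and 10.8 ± 0.763, and the intermediate cell keratin gene Krt13 at 244 ± 19.6 and 577 ± 13.1. These genes were picked after their values were seen.

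Median fold changes between the genotypes differed by chromosome. Of 20 chromosomes, 10 (5, 7, 8, 10, 14, 16, 17, 18, 19 and X) passed a permutation test in both treatments with 1 sign, which argues against chance placement of genes, and 9 also did with the 2505 genes unresponsive to MI-503, which argues against genes that respond to MI-503 gathered on some chromosomes, though that selection ties both contrasts together. The largest shift of a passing autosome, chromosome 8, was 0.29, well under the 0.58 or -1 of 1 chromosome copy more or less in every dKO cell of a diploid line. A copy-number or other line difference in part of the cells may remain, since 74.0% of windows of neighbouring genes had the sign of their chromosome, between the values set for and against it. Among the passing autosomes this share ran from 53.3% on chromosome 10 to 93.75% on chromosome 8. It was 75% on chromosome 12, which did not pass. The windows also make up the median of their chromosome, so agreement is partly built in and the pooled share decides nothing. In the MI-503 contrasts 6 chromosomes also passed in both genotypes, so such shifts are not confined to the genotype.

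The other pattern is genes off in both treatments of 1 genotype, under 0.1 CPM, and on in both of the other, at 5 CPM or more, with thresholds set after the values were seen. They were Adtrp (chromosome 13, 41763145 to 41847616), Pak3 (chromosome X, 143518366 to 143797796), Peg10 (chromosome 6, 4747306 to 4760517) and Ppp1r9a (chromosome 6, 4902872 to 5165661), which were off in labelled dKO cells, and Klf12 and Slitrk5, which were off in WT. By these thresholds 0 genes switched between treatments in both genotypes. Over 16 pairs of thresholds, the genes switching between treatments came to at most 11.8% of those switching between genotypes. This argues against ordinary switching between any 2 groups only as far as the treatments go. The labels do not state whether each genotype is more than 1 line. Ordinary differences between lines can therefore not be told apart from the genotype. Deleted segments stay open, since 2 of the 6, Peg10 and Ppp1r9a, lay next to each other, more than the 0 at the 95th percentile of permuted positions but not most of the genes. Near them, Sgce went from 1.85 to 0.0140 CPM in DMSO, Pon3 from 17.2 to 1.35 and Casd1 from 19.9 to 6.68, while Pon2 went from 81.9 to 112.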
